A study of Mus musculus with 18 samples.

How the data were processed

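The deposited table held 45101 probe sets for each of 18 arrays as linear intensity values. Per the submitters' processing notes, these intensities came from the affy package (version not given), with each array scaled by the authors to a 2% trimmed mean of 500. Splenic CD4 T cells were purified with magnetic beads and, where stimulated, held with anti-CD3 and anti-CD28 for 6 h, per the labels' protocols. The protocols name both a Stratagene kit and Trizol for RNA extraction and 1 ug of RNA for biotin-labelled cRNA. Whether the replicates of a group came from separate mice is not given in the sources used here, so a p-value measures only the spread between these samples. Raw image files were not used here.

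Before the data were examined, the groups, comparisons, settings and 25 gene lists were fixed, with log2 of the value plus 16 and quantile normalization as the rule for linear values. The files held linear values, and this rule was applied. Of the probe sets, 34945 had 1 gene symbol, 932 had several, 9160 had none and 64 were controls, and only those with 1 symbol were used. Entrez numbers matched the reference gene table for 34741 of them and 0 were renamed. Each gene was read from its probe set with the highest mean, which gave 18193 genes. The lists held 442 genes, of which 403 were measured.

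Group means were fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and 13 comparisons were taken from this fit: stimulation in each genotype, the genotypes against each other in each condition, the differences in stimulation effect, and the mean of both conditions. P-values were adjusted by Benjamini and Hochberg within each comparison, and a gene was called at an adjusted p under 0.05. Fold values are differences of log2 means with their standard error (SE). Lists were tested with camera at a preset correlation of 0.01, adjusted over the 25 lists, and again with the correlation estimated from the data. A call was said to be without overlap where the 3 values of a group all lay above or below the 3 of the other. This happens in 10% of unselected genes by chance. Called genes were picked by a small p in the same arrays, which nearly fixes it, so it adds no support to a call. The correlation of the Gli2A and Gli2R effects was compared with 100 simulations that shared the WT arrays.

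Genes were named by a rule. Gli2 was named with each of its probe sets. In each comparison of 3 with 3 arrays, the called genes without overlap (3 of 3 above or below) and with the 10 largest and 10 smallest log2 differences were named, leaving out clone and predicted-gene names. For differences in stimulation effect and means of both conditions only the adjusted p was asked. Where no gene was called, the 5 lowest p-values in each direction were taken, as values only. From each list up to 4 genes with the largest differences were named, and the called ones where fewer than 3 passed. Genes in the figures and in 8 further lists were chosen after the data were seen.

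Limma was run on simulated changes, 100 genes at each size among 18193, with independent noise (a best case). In resting Gli2A Tg against WT it recovered 38% of changes of log2 1 and 86% of log2 2, with 3.12% false calls. In stimulated arrays these were 32%, 81% and 7.38%. Groups of 3 allow no outlier test, and the reported fit kept all arrays.

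Alternative settings were median centring, genes above the median level, eBayes with trend and robust options, array weights, all probe sets one by one, the mean of a gene's probe sets, the replicate number as a block, log2 of the value plus 1 or 64, the arrays of the compared groups alone, and leaving out each array. Deposited scaling only, sex as a covariate, and myeloid and erythroid marker means as covariates were added after the data were seen.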

Results

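Gene expression was measured on Affymetrix arrays in CD4 T cells purified with magnetic beads from the spleens of C57BL/6 mice aged 9 to 15 weeks. The mice were wild type (WT) or carried a transgene for Gli2A or Gli2R. Gli2 is a zinc finger transcription factor at the end of the Hedgehog pathway, and the names Gli2A and Gli2R stand for an activator and a repressor form of it. Cells of each genotype were taken fresh, as resting cells, or after 6 h with antibodies against CD3 and CD28, which engage the T cell receptor complex and a co-stimulatory receptor. The 6 groups had 3 arrays each, 18 in all, and every difference compares 3 arrays with 3 unless a combined effect is named. The median intensity of an array lay between 55.5 and 76.3 on the deposited scale, and the number of arrays limits the precision of each value. No cells cultured for 6 h without antibodies were deposited, so the stimulation effect includes any effect of culture.

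The transgene itself could not be read from the arrays. Gli2 had a pair of probe sets with group means of 4.35 to 5.19 and 4.37 to 5.39 on the log2 scale, below or near the 25th percentile of all genes, 5.37, and the labels do not say which part of Gli2 the transgenes hold. These probe sets therefore check nothing about the labels. Gli1, a transcription factor that Hedgehog signals commonly induce, had group means from 5.95 to 6.42, below the median gene level of 7.06. Ptch1, the Hedgehog receptor and a textbook Gli target, separated the arrays instead. Its mean log2 level was 10.38 ± 0.12 (SD, n = 3) in resting WT, 13.49 ± 0.19 in resting Gli2A Tg and 10.40 ± 0.18 in resting Gli2R Tg cells. After stimulation it was 10.14 ± 0.17, 12.27 ± 0.22 and 10.09 ± 0.14 in the same order.

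Stimulation separated the arrays far more than genotype. The first principal component held 62.8% of the variance and parted the resting from the stimulated arrays, and the next components held 4.85% and 3.26%. Across genes, arrays of 1 group correlated at 0.971 to 0.981, arrays of different genotypes in 1 condition at 0.957 to 0.979, and resting with stimulated arrays at 0.877 to 0.905. Resting Gli2A Tg replicate 3 stood apart on the second component with a score of 55.4, where the next resting array had 11.4. Stimulated Gli2A Tg replicate 2 stood apart on the third with 51, where the next had 16.6, and it had the highest 3' to 5' signal ratio of beta-actin, 3, against 1.82 in the next array, a sign of partly degraded RNA. Male and female mice were unevenly spread: Xist and Y-linked genes gave a male pattern in 2 of 3 resting WT, 1 of 3 stimulated WT and 2 of 3 stimulated Gli2R Tg arrays, and in 0 arrays of the other 3 groups.

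**Figure D1:**
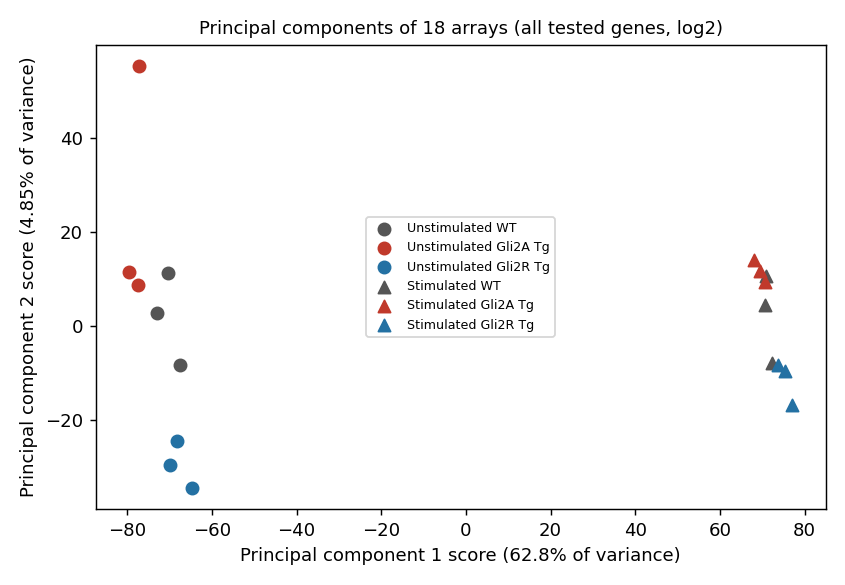
Scores of the 18 arrays on principal components 1 and 2 (62.8% and 4.85% of the variance of all genes; no unit), each point an array, coloured by genotype and marked by condition. Resting and stimulated arrays lie apart on the first component, and resting Gli2A Tg replicate 3 has the highest score on the second, 55.4.

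The first question was how resting CD4 T cells of WT mice change within 6 h of antigen receptor stimulation. Il2, the main T cell growth factor, rose 117-fold (log2 6.87 ± 0.22, SE; adjusted p = 5.01e-11), from a mean log2 level of 6.45 to 13.32. Irf4, a transcription factor that effector T cells need, rose 54.1-fold (5.76 ± 0.25), the orphan nuclear receptor Nr4a3 33.5-fold (5.07 ± 0.17) and Ifng, the signature cytokine of Th1 cells, 38.4-fold (5.26 ± 0.47). Enzyme genes were also among the largest rises, with Ak4, an adenylate kinase, at 6.28 ± 0.38, the prolyl hydroxylase Egln3 at 5.47 ± 0.33 and the branched-chain aminotransferase Bcat1 at 5.46 ± 0.24. Lif (5.6), Mfsd2a (5.56) and Lad1 (5.21) completed the 10 largest. The largest falls were in genes known from macrophages: the complement genes C1qa (-6.83 ± 0.46, 114-fold), C1qc (-6.46) and C1qb (-6.19), the iron exporter Slc40a1 (-6.24 ± 0.22) and the adhesion molecule Vcam1 (-6.13 ± 0.41). Adamdec1 (-6.49), Hebp1 (-6.45), Prg2 (-6.02) and Hpgd (-5.95) fell as far, and Cfp fell by 6.60 on its brightest probe set while its other probe set gave 0.98. In all, 7584 of 18193 genes passed the limma test at an adjusted p (Benjamini-Hochberg) under 0.05, 3576 higher and 4008 lower, 4632 of them by more than 2-fold. Which direction was more frequent depended on the scaling, with 4046 higher and 3858 lower with median centring and 3099 and 4765 with the deposited scaling. The 3 stimulated and 3 resting arrays did not overlap in 7392 of these genes, where chance gives 10% of unselected genes. Centring arrays on their medians in place of quantile normalization moved the median of all genes in this comparison by 0.129 on the log2 scale, which is small beside the changes named here.

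The lists of T cell activation genes rose. Counts adjusted over the list alone are given where they differ from those over all genes. Of 20 activation markers 16 rose and 1 fell (17 and 1 adjusted over the list alone), among them the cytokine Csf2 (4.71 ± 0.37), the co-receptor Tnfrsf9 (3.76 ± 0.19) and the IL-2 receptor chain Il2ra (3.62 ± 0.23). The median was 2.33 and camera gave an adjusted p = 2.18e-09, with adjusted p = 0.0582 with an estimated correlation. Activation-induced transcription factors rose in 14 and fell in 2 of 22 (15 and 3 adjusted over the list alone; median 2.02, adjusted p = 7.63e-06, and adjusted p = 0.199 with an estimated correlation). Fosl2 rose by 4.38 ± 0.20 and Irf8 by 4.23 ± 0.20. NF-kB subunits and targets rose in 12 and fell in 2 of 15 (median 1.39, adjusted p = 0.00022, and adjusted p = 0.237 with an estimated correlation). Nfkbid rose by 4.47 ± 0.23 and Nfkbiz fell by 3.30 on the log2 scale.

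Genes of protein and energy metabolism moved with them. All 22 ribosome biogenesis genes rose (median 1.97, adjusted p = 3.84e-14, and adjusted p = 0.0582 with an estimated correlation), such as Rrp9 (3.34 ± 0.18) and Rrp12 (2.78 ± 0.25). Glycolysis genes rose in 14 of 16 and fell in 0, with hexokinase Hk2 at 4.42 ± 0.23, phosphofructokinase Pfkl at 3.08 ± 0.17 and the glucose transporter Slc2a1 at 2.69 ± 0.18. Their median was 1.62, and this list passed both ways (adjusted p = 3.2e-10, and adjusted p = 0.0483 with an estimated correlation). Of 21 oxidative phosphorylation genes 3 rose and 7 fell. Their median of -0.13 (adjusted p = 0.2) turned to 0.17 with median centring. Cell cycle genes fell in 18 of 21 (median -1.80, adjusted p = 5.36e-07, and adjusted p = 0.257 with an estimated correlation), such as Rrm2, a subunit of ribonucleotide reductase (-4.01 ± 0.37), and Cdk1 (-3.04 ± 0.37). Erythroid precursors also express Rrm2, and of 22 further erythroid genes, listed after the data were seen, 19 fell (median -2.38).

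Genes of the Th1, Th2, Th17 and Tfh subsets rose in WT cells. Th1 genes rose in 11 and fell in 3 of 16 (median 1.78, adjusted p = 0.00482, and adjusted p = 0.128 with an estimated correlation). Ccl3 rose by 4 ± 0.53, Tnf by 3.97 ± 0.30 and Gzmb by 3.38 ± 0.21. Th2 genes rose in 7 and fell in 1 of 15 (7 and 2 adjusted over the list alone; median 0.49, adjusted p = 0.0412, and adjusted p = 0.251 with an estimated correlation). The chemokine receptor Ccr8 rose by 4.38 ± 0.45, Il4 by 2.52 ± 0.37 and Il13 by 2.18 ± 0.49. Ccl3 and Il13 started from mean log2 levels of 4.84 and 5.01, below the 25th percentile of 5.37, so the size of their rises depends on the 16 added before the logarithm. Th17 and Tfh genes rose in 6 and fell in 0 of 10 (median 1.33, adjusted p = 0.00807, and adjusted p = 0.251 with an estimated correlation). Il21 rose by 4.83 ± 0.66 and Il17a by 3.98 ± 0.49. Treg genes went both ways, 3 higher and 4 lower of 14 (median -0.46, adjusted p = 0.559), and the inhibitory receptor Ctla4 rose by 2.45 ± 0.36.

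Genes of naive and resting T cells fell. Naive and quiescence genes rose in 4 and fell in 14 of 20 (5 and 14 adjusted over the list alone; median -1.66, adjusted p = 0.000293, and adjusted p = 0.237 with an estimated correlation), among them the PI3K inhibitor Pik3ip1 (-3.76 ± 0.30), Txnip (-3.70 ± 0.21), the IL-7 receptor Il7r (-3.33 ± 0.13) and the transcription factor Lef1 (-3.24 ± 0.19). Effector and memory genes fell in 15 of 19 and rose in 0 (median -1.84, adjusted p = 1.82e-07, and adjusted p = 0.0582 with an estimated correlation), such as Crip1 (-3.23 ± 0.25) and the integrin Itga4 (-2.71 ± 0.21). T cell receptor signalling components rose in 4 and fell in 11 of 26 (median -0.36, adjusted p = 0.0519), with the diacylglycerol kinase Dgka at -3.32 ± 0.19 and Cd3e at -2.73 ± 0.21. Of 15 Notch pathway genes 2 rose and 4 fell (median -0.26, adjusted p = 0.559), among them the Notch target Dtx1 (-4.22 ± 0.18).

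Among the remaining lists, interferon response genes rose in 11 and fell in 2 of 19 in WT cells (median 1, adjusted p = 0.00374, and adjusted p = 0.199 with an estimated correlation). Cxcl10 rose by 4.56 ± 0.25 and Gbp2 by 2.47 ± 0.31. Apoptosis regulators rose in 8 and fell in 3 of 15 (median 0.41, adjusted p = 0.0458, and adjusted p = 0.176 with an estimated correlation), among them Cdkn1a (3.19 ± 0.28) and the survival gene Bcl2l1 (2.66 ± 0.24). Heat shock genes rose in 6 and fell in 3 of 13 (7 and 3 adjusted over the list alone). Their median, 0.47, and camera's direction were upward while their mean was -0.20 (adjusted p = 0.199), because Hmox1 (-4.26 ± 0.52) and Hspa1b (-2.75 ± 0.44) fell far. Of 19 Hedgehog pathway components 2 rose and 1 fell: the ligand Shh by 2.38 ± 0.48 from a level near the floor, the co-receptor Cdon by 1.05 ± 0.16, and Spop by -1.33 ± 0.14. The median of this list, 0.05, turned to -0.10 with the deposited scaling (adjusted p = 0.74). Textbook Gli targets rose in 2 and fell in 4 of 16 (2 and 3 adjusted over the list alone; median -0.20, adjusted p = 0.74), with the cyclins Ccnd2 at 1.20 ± 0.16 and Ccnd1 at -1.70 ± 0.34.

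Markers of other cells fell with stimulation. Myeloid markers fell in 17 of 18 (18 adjusted over the list alone; median -4.02, adjusted p = 6.39e-11, and adjusted p = 0.0582 with an estimated correlation), such as the Fc receptor Fcgr3 (-5.92 ± 0.36) and the colony-stimulating factor receptor Csf1r (-5.37 ± 0.36), whose mean log2 level was 14.03 in resting WT arrays. B cell markers fell in 7 of 14 (median -1.30, adjusted p = 0.0123, and adjusted p = 0.346 with an estimated correlation). Ly86 fell by 4.84 ± 0.31 on the log2 scale. Erythroid and platelet markers fell in 6 of 11 (7 adjusted over the list alone; median -2.24, adjusted p = 0.0181, and adjusted p = 0.346 with an estimated correlation). The haem synthesis gene Alas2 fell by 3.60 ± 0.59 on the log2 scale. CD8 T and NK cell markers rose in 2 and fell in 5 of 12 (median -0.62, adjusted p = 0.173), and Cd8a rose by 2.05 ± 0.25. The 4 sex-linked genes measured had 0 calls (median -1.23, adjusted p = 0.74), in arrays that differ in sex.

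Stimulation moved the transgenic cells in much the same way. In Gli2A Tg cells 7812 genes passed, 3666 higher and 4146 lower, and in Gli2R Tg cells 7703, 3604 higher and 4099 lower. Of these, 7533 and 7510 had groups that did not overlap (10% of unselected genes by chance). Il2 rose 125-fold in Gli2A Tg (6.96 ± 0.22, adjusted p = 5.41e-11) and 67.5-fold in Gli2R Tg cells (6.08 ± 0.22, adjusted p = 1.45e-10). Ifng rose by 6.12 ± 0.47, Csf2 by 5.67 ± 0.37 and Il21 by 5.45 ± 0.66 in Gli2A Tg cells, while in Gli2R Tg cells Ak4 (5.30), Bcat1 (5.27), Nr4a3 (4.85) and Irf4 (4.81) were among the largest rises. Slc40a1, C1qa, C1qb, C1qc and Hebp1 were among the 10 largest falls in both. In Gli2R Tg cells the pancreatic enzyme gene Cpb1 fell as well (-5.77 ± 1.36, adjusted p = 0.00278), its resting values lying between 5.78 and 12.89 in single arrays. The calls shared by all 3 genotypes were 2526 genes higher and 2992 lower. WT and Gli2A Tg shared 2786 higher and 3286 lower calls against 721 and 913 for independent lists, with 15 in opposite directions. For WT and Gli2R Tg these were 2826 and 3310 against 708 and 903, with 8 opposite. The log2 changes correlated with those of WT across genes, which are not independent replicates, at r = 0.883 for Gli2A Tg and 0.879 for Gli2R Tg, and these comparisons share no arrays.

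Camera passed 16 of 25 lists in WT, 14 in Gli2A Tg and 13 in Gli2R Tg cells under stimulation, and with an estimated correlation glycolysis alone (adjusted p = 0.0483) in WT, effector and memory genes and glycolysis in Gli2A Tg (both at adjusted p = 0.0266) and effector and memory genes in Gli2R Tg (adjusted p = 0.0341). Ribosome biogenesis genes rose in 21 of 22 in Gli2A Tg (median 1.79, adjusted p = 1.32e-11, and adjusted p = 0.115 with an estimated correlation) and in 22 of 22 in Gli2R Tg cells (median 2.15, adjusted p = 3.82e-14, and adjusted p = 0.0727 with an estimated correlation). Cell cycle genes fell in 19 of 21 in Gli2A Tg (1 higher and 19 lower adjusted over the list alone; median -1.41, adjusted p = 4.15e-06, and adjusted p = 0.314 with an estimated correlation) and in 13 of 21 in Gli2R Tg cells, where 1 rose (1 and 14 adjusted over the list alone; median -1.02, adjusted p = 0.0012, and adjusted p = 0.523 with an estimated correlation). Interferon response genes had 3 higher and 6 lower of 19 in Gli2A Tg cells (3 and 7 adjusted over the list alone; median -0.37, adjusted p = 0.491), and in Gli2R Tg cells 12 rose and 3 fell (median 0.88, adjusted p = 0.0184, and adjusted p = 0.381 with an estimated correlation). Th2 genes in Gli2R Tg cells had a median of -0.15, a mean of 0.40 and an upward direction in camera (adjusted p = 0.501), and the median turned to 0.02 with median centring. With median centring the median of all genes in Gli2A Tg cells was 0.111.

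The comparison of resting Gli2A Tg with resting WT cells asks what the activator form changes before stimulation. Ptch1 rose 8.66-fold (log2 3.11 ± 0.16, adjusted p = 9.42e-08), with its probe sets spread from 0.22 to 3.11. Pmepa1, an inhibitor of TGF-beta signalling, rose 8.25-fold (3.04 ± 0.21, adjusted p = 4.27e-06). The fatty acid transporter Slc27a2 rose 11.9-fold (3.58 ± 0.41), Fxyd7, a regulator of the sodium pump, 9.34-fold (3.22 ± 0.38), the organic anion transporter Slco4a1 6.35-fold (2.67 ± 0.32), the granzyme Gzmm 5.98-fold (2.58) and the prostacyclin receptor Ptgir 5.83-fold (2.54). Baiap3 (2.64), Tubb2b (2.19) and Hectd2 (2.11, another probe set at -0.01) were the other large rises. Dapl1 fell 11-fold (-3.46 ± 0.27, adjusted p = 1.3e-05), from a mean log2 level of 11.94 to 8.48. The stress-inducible chaperone genes Hspa1b and Hspa1a fell 16.6-fold (-4.06 ± 0.44, adjusted p = 0.000402) and 8.22-fold (-3.04 ± 0.55, adjusted p = 0.0229). Igfbp4, which binds insulin-like growth factors, fell by 1.5 ± 0.25 on the log2 scale (adjusted p = 0.0116), in 6 of 6 probe sets. Smaller falls were Olfr71 (-1.31), Tmem88 (-1.26), Pramel1 (-1.18), and Chka (-1.69), Tspan1 (-1.45) and Dhx36 (-1.20), each of the last 3 with another probe set above 0.

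By limma 100 genes passed in resting Gli2A Tg against WT cells, 75 higher and 25 lower, 71 of them by more than 2-fold. In all 100 the groups did not overlap (10% of unselected genes by chance), which their selection nearly fixes. Leaving out resting WT replicate 2 left 42 genes and leaving out resting Gli2A Tg replicate 3 left 60. A fit of these 6 arrays alone left 11, and sex as a covariate, chosen after seeing the data, left 40. Ptch1, Pmepa1 and Dapl1 passed in all 19 alternatives. The fit of 6 arrays ended Hspa1b (adjusted p = 0.0996), Slc27a2 (0.131) and Slco4a1 (0.0771), leaving out resting WT replicate 1 or 2 or resting Gli2A Tg replicate 2 or 3 ended Hspa1a (0.0859, 0.125, 0.0676 and 0.0925), and leaving out resting WT replicate 2 or resting Gli2A Tg replicate 3 ended Igfbp4 (0.0564 and 0.0516).

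**Figure D2:**
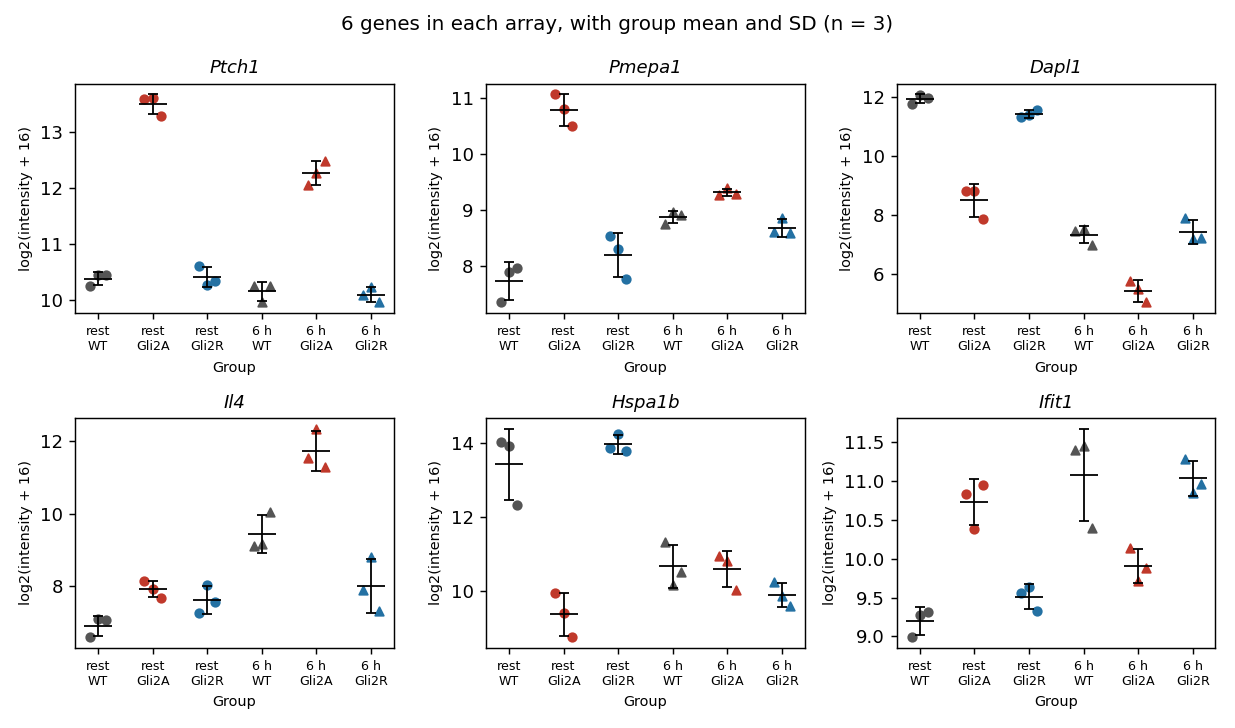
Log2 level of Ptch1, Pmepa1, Dapl1, Il4, Hspa1b and Ifit1 (a panel each; log2 of intensity plus 16 after quantile normalization) in the 6 groups, each point an array and each bar the mean with its SD (n = 3). Ptch1 averages 13.49 in resting and 12.27 in stimulated Gli2A Tg cells against 10.09 to 10.40 in the other 4 groups, and Il4 averages 11.72 in stimulated Gli2A Tg cells.

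Interferon response genes were the clearest group in resting Gli2A Tg cells. Of 19 measured, 17 lay above WT, and Rsad2 (1.96 ± 0.30, adjusted p = 0.00635), Ifit1 (1.53 ± 0.25, adjusted p = 0.0116) and Oasl2 (1.51 ± 0.22, adjusted p = 0.00426) rose, 3 in all and 6 adjusted over the list alone. The list had a median of 0.50 and passed camera (adjusted p = 2.71e-08, and 0.0598 with an estimated correlation). Ifit1 missed without resting Gli2A Tg replicate 3 (adjusted p = 0.0553). Irf8, an activation-induced transcription factor, rose by 1.01 ± 0.20 (adjusted p = 0.0344). All 12 red pulp macrophage genes lay above WT (median 0.66), so other cells may add to these rises. Of the helper subset genes Il18r1 rose by 1.40 ± 0.25 (adjusted p = 0.0199) and Rora by 0.76 ± 0.16 (adjusted p = 0.0451). Il4 at 1 ± 0.37 did not pass (adjusted p = 0.339). Ptch1 was the 1 Hedgehog component of 19 that rose (median 0.07, adjusted p = 0.336), and the 1 Gli target of 16 (2 adjusted over the list alone; median -0.06, mean 0.14 and camera upward, adjusted p = 0.25). Th2 genes had 0 calls, a median of -0.11 and a mean of 0.08 (adjusted p = 0.957).

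In resting Gli2A Tg cells the heat shock list passed downward (2 of 13 lower, 3 adjusted over the list alone; median -0.16, mean -0.61, adjusted p = 0.00106, and adjusted p = 0.243 with an estimated correlation). The immediate-early genes Jun (-2.19, adjusted p = 0.253), Junb (-2.19, adjusted p = 0.0672) and Fos (-2.01, adjusted p = 0.08) did not pass. Across a list of 7 such immediate-early and chaperone genes, written after the data were seen, the array means were 11.43, 10.03 and 9.69 in resting Gli2A Tg and 13.46, 13.12 and 11.75 in resting WT cells. T cell receptor signalling components passed downward with 0 calls (2 lower adjusted over the list alone; median -0.14, adjusted p = 0.00248, and adjusted p = 0.592 with an estimated correlation). Effector and memory genes passed upward with 0 calls (2 higher adjusted over the list alone; median 0.20, adjusted p = 0.0393, and adjusted p = 0.563 with an estimated correlation). Among the markers of other cells, B cell markers had a median of 0.57 with 0 calls (3 adjusted over the list alone; adjusted p = 0.00106, and adjusted p = 0.563 with an estimated correlation). Cd74 lay at 1.46 (adjusted p = 0.0792) and H2-Ab1 at 1.44 (adjusted p = 0.0532). Myeloid markers had a median of 0.37 with 0 calls (adjusted p = 0.012, and 0.563 with an estimated correlation).

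**Figure D3:**
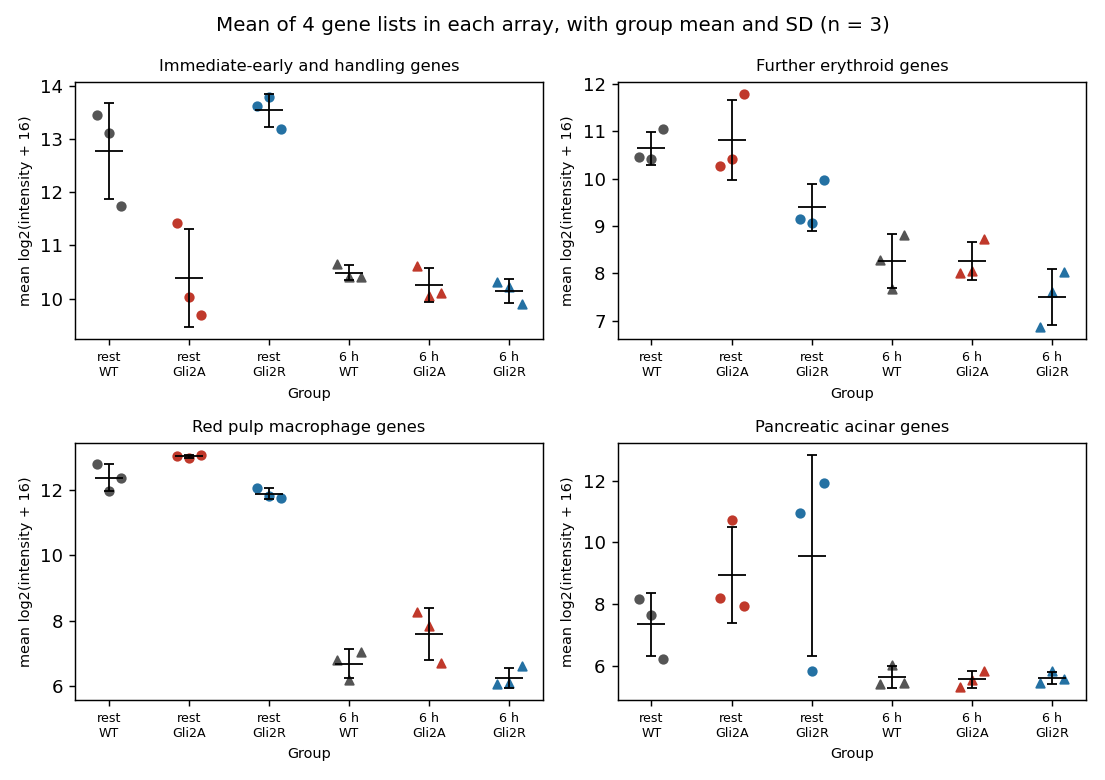
Mean log2 level per array of 4 gene lists written after the data were seen (immediate-early and handling, further erythroid, red pulp macrophage and pancreatic acinar genes; a panel each) in the 6 groups, each point an array. The immediate-early and handling mean is 9.69 to 11.43 in resting Gli2A Tg arrays and 13.20 to 13.80 in resting Gli2R Tg arrays, and the red pulp macrophage mean is 11.75 to 13.08 in resting arrays and 6.06 to 8.26 in stimulated ones.

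After stimulation, Il4, the signature cytokine of Th2 cells, rose 4.86-fold in Gli2A Tg against WT cells (log2 2.28 ± 0.37, adjusted p = 0.0262), from a mean log2 level of 9.44 ± 0.52 to 11.72 ± 0.55 (SD, n = 3). Ptch1 rose 4.35-fold (2.12 ± 0.16, adjusted p = 1.94e-05), with probe sets from 0.34 to 2.12, and Slco4a1 3.98-fold (1.99 ± 0.32, adjusted p = 0.0262). Fam81a (2.23), Fsd2 (1.43), Rab34 (1.35), Plppr1 (1.32) and Ms4a4c (1.28) rose too, and Cd300a (1.71) and Jdp2 (1.41) rose on 1 probe set while another lay below 0. Dapl1 fell 3.74-fold (-1.90 ± 0.27, adjusted p = 0.0217). Acaca, the acetyl-CoA carboxylase that starts fatty acid synthesis, fell by 1.02 ± 0.16, the homeodomain gene Hopx by 0.96 ± 0.15 and Cd52 by 0.73 ± 0.13 on the log2 scale, beside Deup1 (-1.37) and Tdpoz1 (-1.20). In total 25 genes passed in limma, 17 higher and 8 lower, 19 by more than 2-fold. None had overlap between the groups (10% of unselected genes by chance). Leaving out stimulated Gli2A Tg replicate 1 left 11 and replicate 2 left 8, and a fit of the 6 arrays alone left 0. Il4 missed without stimulated WT replicate 1 (adjusted p = 0.0745) or 2 (adjusted p = 0.077), without stimulated Gli2A Tg replicate 1 (adjusted p = 0.0616) or 2 (adjusted p = 0.0991), and over its 19 alternatives the adjusted p ran from 0.00214 to 0.233. Slco4a1 missed without stimulated WT replicate 3 (adjusted p = 0.0776) or stimulated Gli2A Tg replicates 1, 2 or 3 (0.0502, 0.0865 and 0.0661), Dapl1 without stimulated Gli2A Tg replicate 2 (0.0529), Hopx without stimulated WT replicate 3 (0.0686) or stimulated Gli2A Tg replicate 1 or 2 (0.0616 and 0.0651), and Acaca without any of 5 arrays (0.053 to 0.0745).

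Il4 stood alone among Th2 genes. Of 15 measured, Il4 was the 1 that passed, the median was 0.03 (adjusted p = 0.83), and Il13 lay at -1.07 (adjusted p = 0.425). Calls shared with the resting comparison numbered 5 higher and 1 lower, where independent lists would share 0.0701 and 0.011. Interferon response genes now lay below WT in all but 1 of 19, with 0 calls over all genes and 4 lower adjusted over the list alone (median -0.45, adjusted p = 3.26e-07, and adjusted p = 0.0959 with an estimated correlation), Ifit1 at -1.17 (adjusted p = 0.0787) and Ifit3 at -1.06. Th1 genes had 0 calls (1 higher and 6 lower adjusted over the list alone; median -0.46, adjusted p = 0.00119, and adjusted p = 0.113 with an estimated correlation). Ccl3 lay at -1.77 (adjusted p = 0.202) and Gzmb at -0.99 (adjusted p = 0.078). Effector and memory genes had 0 calls (3 lower adjusted over the list alone; median -0.37, adjusted p = 0.00182, and adjusted p = 0.312 with an estimated correlation). S100a6 lay at -1.07 and S100a4 at -1.

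Further lists passed camera in stimulated Gli2A Tg against WT cells, with 0 calls except for Ptch1. Ribosome biogenesis genes had a median of -0.23 (adjusted p = 0.00147) and activation-induced transcription factors of -0.27 (adjusted p = 0.00324), both with adjusted p = 0.586 with an estimated correlation. Without stimulated Gli2A Tg replicate 2, the array with the beta-actin ratio of 3, the ribosome biogenesis median was -0.11. Treg genes (median -0.23, adjusted p = 0.0179), activation markers (-0.16, adjusted p = 0.0429; 2 lower adjusted over the list alone) and NF-kB genes (-0.18, adjusted p = 0.0429) each had adjusted p = 0.591 with an estimated correlation. CD8 T and NK cell markers lay at -0.20 (1 lower adjusted over the list alone; adjusted p = 0.0429, and adjusted p = 0.586 with an estimated correlation). Textbook Gli targets lay at 0.21 with Ptch1 their 1 call (adjusted p = 0.0404, and adjusted p = 0.156 with an estimated correlation), and Hedgehog components at 0.12 with the same call (adjusted p = 0.152). Myeloid markers lay at 0.34 (2 higher and 1 lower adjusted over the list alone; adjusted p = 0.0429, and adjusted p = 0.591 with an estimated correlation). Beside them 12 red pulp macrophage genes, listed after the data were seen, had array means of 8.26, 7.82 and 6.70 in stimulated Gli2A Tg and 6.80, 6.18 and 7.04 in stimulated WT cells.

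Resting Gli2R Tg cells were compared with resting WT cells for the effect of the repressor form, and no single gene passed. The count was 0 in limma, with 1869 genes at an unadjusted p under 0.05. The lowest adjusted p, 0.0654, was that of Haghl (1.53 ± 0.23), Fam20a (1.80 ± 0.27), Abhd1 (1.33), Abca9 (-1.19) and Wdr38 (-1.71), and the eosinophil granule gene Prg2 had -2.58 ± 0.43 (adjusted p = 0.0692). Alkbh2 (1), Abcg3 (-1) and Apoc1 (-1.74) had 0.0774, and Car6 (1.26) 0.0913. Leaving out resting WT replicate 3 gave 14 calls and leaving out resting Gli2R Tg replicate 3 gave 34. Other settings raised the count too, to 46 with the trend and robust options of eBayes and to 212 with array weights.

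Whole lists did shift in resting Gli2R Tg cells, 13 of 25 by camera and 0 with an estimated correlation. Cell cycle genes were the clearest: 21 of 21 lay below WT, 0 passed over all genes and 18 passed adjusted over the list alone (median -0.97, adjusted p = 1.19e-17, and adjusted p = 0.18 with an estimated correlation). Rrm2, which red cell precursors also express, lay at -1.56 ± 0.37 (adjusted p = 0.161) and the mitotic checkpoint kinase Bub1 at -1.40 (adjusted p = 0.245). Erythroid and platelet markers moved the same way (4 lower adjusted over the list alone; median -0.90, adjusted p = 3e-05, and adjusted p = 0.215 with an estimated correlation). Slc4a1 lay at -2.75 ± 0.86 and Alas2 at -2.34 ± 0.59. Myeloid markers also lay below WT (5 lower adjusted over the list alone; median -0.34, adjusted p = 0.000183, and adjusted p = 0.327 with an estimated correlation). S100a8 lay at -2.28. The transferrin receptor Tfrc, used by T cells and by red cell precursors, lay at -1.65 ± 0.32 (adjusted p = 0.1). Heat shock genes had a median of -0.13 (4 lower adjusted over the list alone; adjusted p = 0.0383, and adjusted p = 0.327 with an estimated correlation).

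Helper and effector lists lay above WT in resting Gli2R Tg cells, each with 0 calls over all genes. Th1 genes had a median of 0.41 (5 higher adjusted over the list alone; adjusted p = 0.000183, and adjusted p = 0.161 with an estimated correlation). Ccl3 lay at 2.18 ± 0.53 and Ifng at 1.31 ± 0.47. Th17 and Tfh genes had 0.38 (3 higher adjusted over the list alone; adjusted p = 0.00025, and adjusted p = 0.218 with an estimated correlation). Il21 lay at 2.22 ± 0.66 and Ascl2 at 2.35 ± 0.55, with an SD among the 3 Gli2R Tg arrays of 1.84 and 1.49. Treg genes had 0.43 (2 higher adjusted over the list alone; adjusted p = 0.00162, and adjusted p = 0.4 with an estimated correlation). Il10 lay at 1.47 ± 0.43, with an SD of 1.11. All 7 immediate-early and chaperone genes lay above WT as well (median 0.72, 0 calls). Effector and memory genes had 0.39 (3 higher adjusted over the list alone; adjusted p = 3e-05, and adjusted p = 0.18 with an estimated correlation). CD8 T and NK cell markers had 0.33 (1 higher adjusted over the list alone, adjusted p = 0.0176). Activation markers had 0.36 (3 higher and 1 lower adjusted over the list alone, adjusted p = 0.00224). Both had adjusted p = 0.327 with an estimated correlation. Activation-induced transcription factors had 0.33 (1 higher adjusted over the list alone; adjusted p = 0.00766, and adjusted p = 0.463 with an estimated correlation). T cell receptor signalling components had 0.18 (adjusted p = 0.00224) and naive genes 0.17 (adjusted p = 0.0242). With an estimated correlation their adjusted p was 0.482 and 0.475.

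Stimulated Gli2R Tg and WT cells differed in 8 genes by limma, 3 higher and 5 lower, 7 by more than 2-fold. All were without overlap between the groups (10% of unselected genes by chance). Ankrd66 rose 2.51-fold (1.33 ± 0.21), Cavin4 2.5-fold (1.32) and Bbs4, a component of the ciliary BBSome complex, 2.18-fold (1.12 ± 0.18), the last with another probe set at -0.05. Gstt1, a glutathione transferase, fell 3.82-fold (-1.93 ± 0.29), the cannabinoid receptor Cnr2 2.46-fold (-1.30 ± 0.21) and Tdpoz1 2.34-fold (-1.23), each at an adjusted p = 0.0487. The count was 0 without stimulated WT replicate 3 or stimulated Gli2R Tg replicate 3, 4 without stimulated WT replicate 2, 3 without stimulated Gli2R Tg replicate 1 and 14 without its replicate 2. It was also 0 with median centring (median of all genes -0.109) and in the fit of the 6 arrays alone. Gstt1 missed without any stimulated WT array or stimulated Gli2R Tg replicate 1 or 3 (adjusted p = 0.0806 to 0.129), and Bbs4 without stimulated WT replicate 1 or 3 or any stimulated Gli2R Tg array (0.057 to 0.161). Il4 (-1.42 ± 0.37, adjusted p = 0.225), Il13 (-1.96, adjusted p = 0.219), Il5 (-1.29), Ifng (-1.23) and Il2 (-0.79, adjusted p = 0.253) did not pass.

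Several lists lay lower in stimulated Gli2R Tg than in WT cells, with 0 calls over all genes. Th2 genes had a mean of -0.41 and a median of -0.06 (4 lower adjusted over the list alone; adjusted p = 0.0379, and adjusted p = 0.497 with an estimated correlation). Th1 genes (median -0.34, 1 lower adjusted over the list alone) and glycolysis genes (-0.24) both had adjusted p = 0.0122, and adjusted p = 0.497 with an estimated correlation. Activation markers (-0.25), cell cycle genes (-0.21) and heat shock genes (-0.23) had adjusted p = 0.0217, and in turn adjusted p = 0.638, 0.679 and 0.497 with an estimated correlation. The further erythroid genes had a median of -0.81, with 2 of 22 above 0. Effector and memory genes had -0.21 (1 lower adjusted over the list alone; adjusted p = 0.0384, and adjusted p = 0.638 with an estimated correlation). Of the 7 lists, 3 passed when the probe sets of a gene were averaged.

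The direct comparison of the activator with the repressor form gave the most calls between genotypes. In resting cells Ptch1 was 8.51-fold higher in Gli2A Tg than in Gli2R Tg cells (3.09 ± 0.16, adjusted p = 1.05e-07), Rsad2, an interferon-induced antiviral gene, 12.5-fold (3.64 ± 0.30, adjusted p = 2e-05), Slc27a2 15.8-fold (3.98) and Fxyd7 by 2.94 on the log2 scale. The red cell genes Alas2 (4.18 ± 0.59, adjusted p = 0.00194), Slc4a1 (3.80 ± 0.86, adjusted p = 0.0322, another probe set at -0.05), Slc25a37 (3.29) and Bpgm (2.71) rose as far, beside Apol11b (3.28) and Gda (3.25). Hspa1b was 24.1-fold lower (-4.59 ± 0.44, adjusted p = 6.71e-05), Hspa1a 15.9-fold (-3.99 ± 0.55), Jun 11.4-fold (-3.51 ± 0.71, adjusted p = 0.018), Dusp1 7.8-fold (-2.96), Dapl1 7.68-fold (-2.94 ± 0.27) and Ifng 6.66-fold (-2.74 ± 0.47, adjusted p = 0.00685). Junb (-2.90), Fos (-2.46), Cnga1 (-2.36) and Fam20a (-2.08) fell too. By limma 436 genes passed, 285 higher and 151 lower, 250 by more than 2-fold, without overlap between the groups in each (10% by chance). Of these, 64 higher and 20 lower genes were also called between resting Gli2A Tg and WT cells, where independent lists would share 1.17 and 0.207, although part of the excess may come from the Gli2A Tg arrays that both comparisons use. Leaving out resting Gli2A Tg replicate 3 gave 180, resting Gli2R Tg replicate 1 gave 279 and its replicate 2 gave 156, and myeloid and erythroid marker means as covariates, chosen after seeing the data, left 3, with Ptch1 kept and Jun at -3.57 (adjusted p = 0.882), Hspa1b at -4.37 (0.22) and Rsad2 at 2.84 (0.254). Alas2 and Slc4a1 belong to the erythroid markers and cannot be judged by this setting. Slc4a1 missed without resting Gli2A Tg replicate 2 or 3 or resting Gli2R Tg replicate 1 or 2 (adjusted p = 0.0547, 0.137, 0.0579 and 0.135), and so did Jun (0.0539, 0.091, 0.0584 and 0.0855).

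By group, resting Gli2A Tg cells had higher interferon response genes than Gli2R Tg cells in 4 of 19 (5 adjusted over the list alone; median 0.37, adjusted p = 2.79e-05, and adjusted p = 0.286 with an estimated correlation), among them Oasl2 (1.39), Ifit1 (1.21) and Irf7 (0.73). Ifit1 missed without resting Gli2A Tg replicate 3 or any resting Gli2R Tg array (adjusted p = 0.0516 to 0.0952). Cell cycle genes lay above in 21 of 21, with 1 call, Rrm2 at 1.58 (median 0.75, adjusted p = 1.85e-08, and adjusted p = 0.485 with an estimated correlation). Resting Gli2A Tg replicate 3, which stood apart, had the highest mean of these genes, 11.65 against 10.41 and 10.59, and without it the median was 0.39. T cell receptor signalling components fell in 2 of 26 (11 adjusted over the list alone; median -0.26, adjusted p = 7.51e-07, and adjusted p = 0.485 with an estimated correlation), which were Cblb (-1.28) and Cd5 (-0.85). Naive genes fell in 3 of 20 (1 higher and 5 lower adjusted over the list alone; median -0.39, adjusted p = 0.00322, and adjusted p = 0.539 with an estimated correlation), including Klf2 (-1.08) and Ccr7 (-0.97). Treg genes fell in 3 of 14 (4 adjusted over the list alone; median -0.42, adjusted p = 0.00363, and adjusted p = 0.624 with an estimated correlation), including Il10 (-1.75) and Tnfrsf18 (-0.86). Activation-induced transcription factors rose in 1 and fell in 4 of 22 (1 and 6 adjusted over the list alone; median -0.27, adjusted p = 0.00321, and adjusted p = 0.582 with an estimated correlation). Activation markers fell in 1 of 20, Cd69 by 1.62 on the log2 scale (1 higher and 3 lower adjusted over the list alone; median -0.23, adjusted p = 0.0451, and adjusted p = 0.641 with an estimated correlation). NF-kB genes had a median of -0.30 (3 lower adjusted over the list alone; adjusted p = 0.0451, and adjusted p = 0.666 with an estimated correlation). Heat shock genes fell in 2 of 13, while their median was 0.09 and their mean -0.53 (camera downward, adjusted p = 0.599).

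Markers of other cells differed between the resting Gli2A Tg and Gli2R Tg arrays beside these groups. Myeloid markers were higher in 3 of 18 (8 adjusted over the list alone; median 0.90, adjusted p = 1.28e-07, and adjusted p = 0.286 with an estimated correlation), including Adgre1 (1.48) and Fcer1g (1.19). Erythroid and platelet markers were higher in 2 of 11 (3 adjusted over the list alone; median 0.97, adjusted p = 5.9e-05, and adjusted p = 0.362 with an estimated correlation). B cell markers had 0 calls (3 higher adjusted over the list alone; median 0.35, adjusted p = 0.0313, and adjusted p = 0.635 with an estimated correlation). The means of the 7 immediate-early and chaperone genes were 10.38 in resting Gli2A Tg and 13.54 in resting Gli2R Tg cells, on a list written mostly from genes seen to fall here.

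In stimulated cells Il4 was 13-fold higher in Gli2A Tg than in Gli2R Tg cells (3.70 ± 0.37, adjusted p = 0.000587), with WT cells between them. Ptch1 was 4.53-fold higher (2.18 ± 0.16, adjusted p = 1.34e-05), and Slco4a1 (2.49), the growth factor Tgfb3 (2.45), Gpat3 (2.08), the leukotriene receptor Cysltr1 (2.03) and Gstt1 (1.94) rose as well. Cfp (2.60) rose, and Mid1 (2.23) and Mef2c (1.94) each had a probe set below 0. Dapl1 fell 3.99-fold (-2 ± 0.27, adjusted p = 0.00751), the actin regulator Cotl1 by 1.02 ± 0.14, Morn4 by 1.51, Cd52 by 0.77 and Col4a4 by 1.55 on the log2 scale, the last with another probe set at 0.02. The count was 42, 36 higher and 6 lower, 33 by more than 2-fold, all without overlap between the groups (10% by chance). Of these genes, 5 higher and 2 lower were also called between stimulated Gli2A Tg and WT cells (0.0336 and 0.00264 for independent lists), part of which may come from the stimulated Gli2A Tg arrays that both use, and 10 higher and 1 lower in the resting comparison of Gli2A Tg with Gli2R Tg (0.564 and 0.0498). Leaving out stimulated Gli2A Tg replicate 1 gave 27, replicate 2 gave 21, replicate 3 gave 71, and leaving out stimulated Gli2R Tg replicate 1 gave 24 and ended Gstt1 (adjusted p = 0.0557). The fit of the 6 arrays alone gave 0.

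Hedgehog components (1 higher of 19, 2 adjusted over the list alone; median 0.12, adjusted p = 0.0419) and textbook Gli targets (1 higher of 16, 2 adjusted over the list alone; median 0.26, adjusted p = 0.0168) passed camera in stimulated Gli2A Tg against Gli2R Tg cells, both with adjusted p = 0.188 with an estimated correlation. Ptch1 was the call in each. Th2 genes had 1 call, Il4 (3 higher adjusted over the list alone; median 0.28, adjusted p = 0.0312, and adjusted p = 0.326 with an estimated correlation). Glycolysis genes had a median of 0.29 (2 higher adjusted over the list alone; adjusted p = 0.000575, and adjusted p = 0.219 with an estimated correlation). Interferon response genes had -0.19 (2 lower adjusted over the list alone; adjusted p = 0.00039, and adjusted p = 0.188 with an estimated correlation). Ribosome biogenesis genes lay at -0.12, or 0.01 with median centring (adjusted p = 0.00792), Treg genes at -0.32 (adjusted p = 0.0312), cell cycle genes at 0.22 (adjusted p = 0.0419) and B cell markers at 0.54 (adjusted p = 0.0475), all with adjusted p = 0.594 with an estimated correlation. The further erythroid genes lay at 0.68 beside the cell cycle genes, 21 of 22 above 0. Myeloid markers lay at 0.66 (6 higher and 1 lower adjusted over the list alone; adjusted p = 0.000135, and adjusted p = 0.303 with an estimated correlation).

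Whether the genotypes responded differently to stimulation was tested as the difference of the stimulation effects. In Gli2A Tg against WT cells 2 genes passed in limma, both lower. Pmepa1 (-2.60 ± 0.30, adjusted p = 0.00634) averaged 7.74 in resting and 8.87 in stimulated WT cells but 10.78 and 9.31 in Gli2A Tg cells. Ifit1, an interferon-induced gene, (-2.70 ± 0.35, adjusted p = 0.0167) went from 9.20 to 11.08 in WT and from 10.73 to 9.91 in Gli2A Tg cells, and it missed without resting WT replicate 2 (adjusted p = 0.0586) or stimulated Gli2A Tg replicate 3 (adjusted p = 0.0776). The Ptch1 and Il4 effects were not shown to differ between resting and stimulated cells, at -0.99 ± 0.22 (adjusted p = 0.139) and 1.28 ± 0.52 (adjusted p = 0.43). Interferon response genes as a list passed with 19 of 19 below 0, 1 over all genes and 11 adjusted over the list alone (median -0.85, adjusted p = 2.22e-14), and they also passed with an estimated correlation (adjusted p = 0.00705). The 7 immediate-early and chaperone genes, which differed between the resting arrays, had a median of 2.10 in the same comparison, 7 of 7 above 0. The count was 1 without resting WT replicate 2 or stimulated Gli2A Tg replicate 3, and 4 without resting WT replicate 1, stimulated WT replicate 2 or stimulated Gli2A Tg replicate 2. It was 5 without resting Gli2A Tg replicate 2 or stimulated WT replicate 1, 6 without resting Gli2A Tg replicate 3, 8 without resting WT replicate 3 and 14 without resting Gli2A Tg replicate 1.

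Th1 genes (0 calls, 6 lower adjusted over the list alone; median -0.53, adjusted p = 7.57e-05, and adjusted p = 0.0511 with an estimated correlation) and effector and memory genes (0 calls, 4 lower adjusted over the list alone; median -0.52, adjusted p = 6.77e-05, and adjusted p = 0.151 with an estimated correlation) also responded lower in Gli2A Tg than in WT cells by camera. CD8 T and NK cell markers had a median of -0.46 (adjusted p = 0.0286, and adjusted p = 0.592 with an estimated correlation). Ribosome biogenesis genes had -0.28 (adjusted p = 0.029, and adjusted p = 0.852 with an estimated correlation). Oxidative phosphorylation genes had 0.15 (1 higher adjusted over the list alone; adjusted p = 0.029, and adjusted p = 0.839 with an estimated correlation). T cell receptor signalling components had 0.18 (adjusted p = 0.0454, and adjusted p = 0.852 with an estimated correlation).

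In Gli2R Tg against WT cells 0 genes passed in limma for the difference of the stimulation effects, with 1574 at an unadjusted p under 0.05. The lowest adjusted p, 0.133, included Abca9 (1.61), Cavin4 (1.71), Haghl (-2.07) and the protease gene Ctsw (-1.82). Without resting Gli2R Tg replicate 3 the count was 12, it was 2 without stimulated Gli2R Tg replicate 2 or 3, and 1 without resting WT replicate 3, resting Gli2R Tg replicate 1, stimulated WT replicate 1 or 2, or stimulated Gli2R Tg replicate 1. Of the lists, 11 passed. Th1 genes had 0 calls and 7 lower adjusted over the list alone (median -0.77, adjusted p = 4.1e-06), and passed with an estimated correlation too (adjusted p = 0.0345), beside -0.98 with 0 of 7 above 0 for the immediate-early and chaperone genes. Ccl3 lay at -3.27 and Ifng at -2.54. Th17 and Tfh genes had a median of -0.84 (3 lower adjusted over the list alone; adjusted p = 6.36e-05, and adjusted p = 0.253 with an estimated correlation). Il21 lay at -3.43. Th2 genes had a median of -0.29 (3 lower adjusted over the list alone; adjusted p = 0.0125, and adjusted p = 0.28 with an estimated correlation). Il4 lay at -2.12 ± 0.52 (adjusted p = 0.284). Effector and memory genes had -0.53 (4 lower adjusted over the list alone; adjusted p = 4.1e-06, and adjusted p = 0.121 with an estimated correlation). Cell cycle genes had 0.58 with 21 of 21 above 0 (adjusted p = 6e-06, and adjusted p = 0.386 with an estimated correlation), beside 0.57 with 19 of 22 above 0 for the further erythroid genes. With median centring the median of all genes here was -0.122.

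The other lists that passed for Gli2R Tg had 0 calls over all genes. Activation markers had a median of -0.42 (1 higher and 3 lower adjusted over the list alone; adjusted p = 6.36e-05, and adjusted p = 0.28 with an estimated correlation). Activation-induced transcription factors had -0.41 (1 lower adjusted over the list alone; adjusted p = 0.00259, and adjusted p = 0.386 with an estimated correlation). CD8 T and NK cell markers had -0.44 (4 lower adjusted over the list alone; adjusted p = 0.0284, and adjusted p = 0.379 with an estimated correlation). Treg genes had -0.46 (adjusted p = 0.0126) and NF-kB genes -0.20 (1 lower adjusted over the list alone; adjusted p = 0.026), both with adjusted p = 0.466 with an estimated correlation. Glycolysis genes had -0.24 (adjusted p = 0.0209, and adjusted p = 0.379 with an estimated correlation).

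Averaged over both conditions, the Gli2A effect against WT reached 110 genes in limma, 82 higher and 28 lower, 42 by more than 2-fold. Ptch1 rose 6.14-fold (2.62 ± 0.11, adjusted p = 8.11e-09), Slc27a2 6.16-fold (2.62 ± 0.29), Slco4a1 5.03-fold (2.33), and Fam81a (2.16), Fxyd7 (1.91), Tgfb3 (1.82), Baiap3 (1.82), Ptgir (1.80), Pmepa1 (1.74) and Hectd2 (1.69) followed. Dapl1 fell 6.41-fold (-2.68 ± 0.19, adjusted p = 7.53e-06), and Hspa1b (-2.06), Lbp (-1.54), Igfbp4 (-1.33), the chemokine Ccl1 (-1.25) and Gapdhs (-1.22) fell less. Il4 rose by 1.64 ± 0.26 (adjusted p = 0.00763), Fasl by 0.73, Rora by 0.58 and Igf1r by 0.80, while Il7r fell by 0.44 on the log2 scale. Leaving out resting WT replicate 2 gave 64 and stimulated Gli2A Tg replicate 2 gave 65. B cell markers (0 calls, 5 higher adjusted over the list alone; median 0.53) and heat shock genes (1 lower, 3 adjusted over the list alone; median -0.18) had adjusted p = 0.00178, and in turn adjusted p = 0.609 and 0.31 with an estimated correlation. Myeloid markers had a median of 0.42 (5 higher adjusted over the list alone; adjusted p = 0.00289, and adjusted p = 0.646 with an estimated correlation). Activation-induced transcription factors had -0.14 (3 lower adjusted over the list alone; adjusted p = 0.00762, and adjusted p = 0.723 with an estimated correlation). Ribosome biogenesis genes had -0.09 (adjusted p = 0.0287, and adjusted p = 0.818 with an estimated correlation).

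For Gli2R Tg the average over both conditions gave 0 genes in limma, with 1902 at an unadjusted p under 0.05. The lowest adjusted p was 0.194, with Sdk2 (0.94), Macf1 (0.72), the Cd28 ligand gene Cd86 (-0.76) and Tspan4 (-0.78) among the genes at it. Without resting WT replicate 3 the count was 6, without resting Gli2R Tg replicate 3 it was 5, and it was 1 without stimulated WT replicate 1 or stimulated Gli2R Tg replicate 2. Cell cycle genes had a median of -0.71 with 0 calls (16 lower adjusted over the list alone; adjusted p = 1.2e-14, and adjusted p = 0.332 with an estimated correlation). Erythroid and platelet markers had -0.98 (6 lower adjusted over the list alone; adjusted p = 7e-05, and adjusted p = 0.332 with an estimated correlation). Myeloid markers had -0.29 (adjusted p = 7e-05, and adjusted p = 0.408 with an estimated correlation). Heat shock genes had -0.15 (2 lower adjusted over the list alone; adjusted p = 0.00186, and adjusted p = 0.332 with an estimated correlation). T cell receptor signalling components (0.15, adjusted p = 0.000749) and naive genes (0.15, adjusted p = 0.0137) had adjusted p = 0.868 with an estimated correlation.

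The Gli2A and Gli2R effects were also set beside each other across all genes, which are not independent replicates. In resting cells they correlated at r = 0.302, where 100 simulations of unchanged groups against the same WT arrays gave 0.48 on average (-0.293 to 0.88), and the covariance was 0.0464 against a simulated 0.0562, a difference of -0.00977. In stimulated cells r was 0.503 against 0.481 (-0.145 to 0.854), and the covariance 0.0796 against 0.0583, a difference of 0.0212. The calls shared by stimulated Gli2A Tg and Gli2R Tg cells against WT were 0 higher and 3 lower, where independent lists would share 0.0022 lower genes, and part of this excess may come from the 3 WT arrays that both effects use.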

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

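Of the tests given here, those of cell handling, sex of the mice, a lower share of T cells, the array with the most degraded RNA, a Th2 programme, the parts of the immediate-early list and list medians without 1 array were chosen only after the result was seen, and the others were written before their values were computed, on lists chosen after the data were seen or on regrouped arrays.

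Immediate-early genes, Hspa1a and Hspa1b were lower in resting Gli2A Tg than Gli2R Tg arrays, and cell handling before lysis may explain it. Across 7 such genes the range within the 3 resting WT arrays was 0.54 of the difference between the transgenic groups (1.71 against -3.16), so arrays of 1 genotype differed on the same genes. A separate list of 15 genes had a median of -0.83 with a spread of 0.22, as a general immediate-early response would give, from its 11 immediate-early genes (-0.99) and not its 4 chaperone and co-chaperone genes (0.48). Sex of the mice is an unlikely source, since the difference between these groups in the number of male-pattern arrays was 0. Lysing cells of all genotypes at fixed times after isolation would separate handling from genotype, and Hspa1b, Hspa1a, Jun and Fos carry this limit.

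Erythroid genes were higher in resting Gli2A Tg than in Gli2R Tg arrays, and more erythroid cells in the preparation may explain it. A separate list held 22 erythroid genes, 0 in a fixed list and 22 above the median level in resting WT arrays. Their median was 1.41 with a spread of 0.17, or 0.99 without resting Gli2A Tg replicate 3. Against WT the median was 0.15 in Gli2A Tg and -1.16 in Gli2R Tg, so the gap lay mostly in a low Gli2R Tg level. Array means were 10.26, 10.41 and 11.78 in Gli2A Tg and 9.14, 9.06 and 9.97 in Gli2R Tg. Spreads here are over genes, not arrays. A lower share of T cells stays open, since other cells need not rise alike. The smaller of the myeloid (0.90) and B cell (0.35) medians lay -1.06 from the erythroid one (spread 0.27). Sorting CD4 cells by flow cytometry would remove these cells, and cell cycle genes such as Rrm2, which erythroid precursors also express, carry this limit.

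Il4 was higher in stimulated Gli2A Tg than in WT cells, and basophils or mast cells in the preparation could make part of it, which stays open: 11 of their genes had a median of 0.24 with a spread of 0.2, 7 of them above 0, 0 called and 0 in a fixed list. The genes ran from Ms4a2 0.53, Csf2rb 0.47 and Cpa3 0.46 to Fcer1a -0.32, Gata2 -0.37 and Cyp11a1 -0.5. Without stimulated Gli2A Tg replicate 2 (most degraded RNA) the Il4 difference kept 0.859 of its size, at an adjusted p = 0.0991. The Th2 genes other than Il4 had a median of 0.02 with a spread of 0.093, so a Th2 programme as a whole was not seen at 6 h. Sorting CD4 cells would remove basophils and mast cells, and IL-4 staining would show which cells make it.

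The response to stimulation was tested for differences between genotypes, and in Gli2A Tg against WT cells Ifit1 (-2.70) and Pmepa1 (-2.60) passed in limma. Among lists, camera passed interferon response genes (-0.85), Th1 genes (-0.53), effector and memory genes (-0.52), CD8 T and NK cell markers (-0.46), ribosome biogenesis genes (-0.28), oxidative phosphorylation genes (0.15) and T cell receptor signalling components (0.18). With an estimated correlation interferon response genes alone passed (adjusted p = 0.00705, the others 0.0511 to 0.852). In Gli2R Tg cells it passed Th17 and Tfh genes (-0.84), Th1 genes (-0.77), effector and memory genes (-0.53), Treg genes (-0.46), CD8 T and NK cell markers (-0.44), activation markers (-0.42), activation-induced transcription factors (-0.41), Th2 genes (-0.29), glycolysis genes (-0.24), NF-kB genes (-0.20) and cell cycle genes (0.58). Of these Th1 genes alone passed with an estimated correlation (adjusted p = 0.0345, the others 0.121 to 0.466). Handling genes moved with the Th1 genes (-0.98) and further erythroid genes with the cell cycle genes (0.57). The cause was not tested.

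The arrays of each comparison were also regrouped. In comparisons of 3 with 3 arrays the 10 splits possible are too few for a share under 0.05. The real and the highest other counts were 7584 and 0 for stimulation in WT, 7812 and 2 in Gli2A Tg and 7703 and 1 in Gli2R Tg cells, each real count reached in 1 of 10 splits. In the same form they were 100 and 4 for resting and 25 and 3 for stimulated Gli2A Tg against WT, and 436 and 13 for resting and 42 and 11 for stimulated Gli2A Tg against Gli2R Tg (1 of 10 each). For Gli2R Tg against WT they were 0 and 2 in resting (10 of 10) and 8 and 8 in stimulated cells (2 of 10). Over 100 splits drawn from those possible, the 110 genes of the mean Gli2A effect were reached in 1, the real grouping, with 14 as the highest other. The 2 genes of its difference in stimulation effect were reached in 11 (highest other 14). Chance is thus unlikely for the former alone, if the arrays can be exchanged, and is not excluded. The 0 genes of the Gli2R mean and difference were reached in 100 and 100 (highest other 1 and 4).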

How the results depend on the processing

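Of the settings given here, deposited scaling only, sex as a covariate and marker means as covariates, and the tests with them, were chosen only after the result was seen. On the probe set that stands for each gene, the named genes kept their direction: of 3626 alternatives to 188 passing results 2863 kept the call, 763 lost it and 0 reversed, and of 675 alternatives to 30 results that did not pass 66 passed and 0 reversed. Other probe sets of the same gene did not always go the same way, as for Cfp with stimulation in WT (-6.60 and 0.98), Jdp2 (1.41 and -0.98) and Cd300a (1.71 and -0.43) in stimulated Gli2A Tg against WT, and all probe sets of 5 of 9 named genes with several shared a direction in resting Gli2A Tg against WT. Counts moved more than directions. Settings that drop genes near the floor or shrink their spread raised most counts, and the cause was not tested.

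Testing all probe sets one by one gave 15943, 16437 and 16205 calls for stimulation in WT, Gli2A Tg and Gli2R Tg. It gave 12 for resting Gli2R Tg against WT, 54 and 27 for stimulated Gli2A Tg and Gli2R Tg against WT, 27 for stimulated Gli2A Tg against Gli2R Tg, 6 and 1 for the differences in stimulation effect of Gli2A Tg and Gli2R Tg, and 1 for the Gli2R mean. Averaging the probe sets of a gene, which counts genes again, gave 13 for stimulated Gli2A Tg against WT and 23 against Gli2R Tg, and 3 lists for stimulated Gli2R Tg against WT.

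In the order resting Gli2A Tg and Gli2R Tg against WT, stimulated Gli2A Tg and Gli2R Tg against WT, resting and stimulated Gli2A Tg against Gli2R Tg, Gli2A and Gli2R difference in stimulation effect, and Gli2A mean, genes above the median level gave 187, 48, 139, 0, 1007, 121, 45, 1 and 225. That setting tested only part of the 18193 genes. The trend and robust options of eBayes gave 174, 46, 170, 16, 884, 137, 34, 7 and 219, and log2 of value plus 64 gave 206, 16, 54, 0, 930, 103, 38, 2 and 200.

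Array weights gave 212 for resting Gli2R Tg against WT, 51 for stimulated Gli2A Tg against WT, 132 for stimulated Gli2A Tg against Gli2R Tg and 7 for the Gli2A difference. Median centring gave 6 for resting Gli2R Tg, 14 and 0 for stimulated Gli2A Tg and Gli2R Tg against WT, 4 for the Gli2A difference and 73 for the Gli2A mean. With log2 of value plus 1 there were 2 for resting and 4 for stimulated Gli2R Tg against WT, and with deposited scaling only 1 and 0.

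A fit of only the arrays of the groups compared gave 11 for resting Gli2A Tg against WT, 0 and 0 for stimulated Gli2A Tg and Gli2R Tg against WT, 51 and 0 for resting and stimulated Gli2A Tg against Gli2R Tg, and 68 for the Gli2A mean. Sex as a covariate gave 40 for resting Gli2A Tg and 0 for stimulated Gli2R Tg against WT, 4 for stimulated Gli2A Tg against Gli2R Tg and 52 for the Gli2A mean. Myeloid and erythroid marker means as covariates gave 43 and 10 for resting and stimulated Gli2A Tg and 1 for stimulated Gli2R Tg against WT, 3 and 4 for resting and stimulated Gli2A Tg against Gli2R Tg, 4 for the Gli2A difference and 46 for the Gli2A mean.

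The replicate numbers as a block gave 28 for resting and 0 for stimulated Gli2R Tg against WT and 19 for the Gli2R mean. Of 45 pairs with the same number 14 correlated above 0.1 after group means were removed (-0.12 to 0.31), and 3 of 9 resting and stimulated pairs differed in sex, so that those were not the same mouse. As a hint from the data, 13 of 18 arrays correlated best with an array of their own number, and the mean of 22 further erythroid genes was highest in replicate 3 of each of the 6 groups. By the labels the arrays share only a number, and whether a number stands for a shared day or batch is not given in the sources used here.

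With the correlation of list genes estimated, the lists passing camera went from 16 to 1, 14 to 2 and 13 to 1 for stimulation in WT, Gli2A Tg and Gli2R Tg, from 6 and 13 to 0 and 0 for resting Gli2A Tg and Gli2R Tg against WT, from 11 and 7 to 0 and 0 for stimulated ones, from 11 and 10 to 0 and 0 for Gli2A Tg against Gli2R Tg, from 7 and 11 to 1 and 1 for the differences, and from 5 and 6 to 0 and 0 for the means.

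Leaving out 1 array gave 42 to 91 calls for resting Gli2A Tg and 0 to 34 for resting Gli2R Tg against WT, 8 to 36 and 0 to 14 for stimulated ones, 156 to 609 and 21 to 71 for Gli2A Tg against Gli2R Tg, 1 to 14 and 0 to 12 for the differences, and 64 to 122 and 0 to 6 for the means.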

Other observations

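Genes induced by low oxygen and genes of amino acid supply rose together after 6 h of stimulation. Of 14 hypoxia-inducible genes 11 rose in each genotype by limma, with medians of 2.17 in WT, 2.49 in Gli2A Tg and 2.02 in Gli2R Tg cells. Of 15 genes of one-carbon and amino acid metabolism 13 rose in each, with medians of 1.80, 1.72 and 1.85. Both lists were written after the data were seen and hold 2 genes each that are named among the largest changes, such as Ak4, Egln3 and Bcat1. Of the 12 other hypoxia-inducible genes 9 rose in each genotype (medians 1.67, 2.21 and 1.70), and of the 13 others of one-carbon and amino acid metabolism 11 (1.68, 1.72 and 1.72). The tests of these lists were chosen only after the result was seen.

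Red pulp macrophage genes were abundant in resting arrays. Of the 12 listed, 7 are named among the largest changes, such as C1qa and Slc40a1, and the other 5 fell with stimulation in each genotype too (medians -5.36, -4.95 and -4.95). In stimulated cells the median of the 12 lay 1.13 above WT and 1.40 above Gli2R Tg in Gli2A Tg arrays, with 0 genes called in either comparison, and Gli2A Tg replicate 3 (6.70) lay below WT replicates 1 (6.80) and 3 (7.04). Pancreatic acinar genes had array means of 10.72 in resting Gli2A Tg replicate 2, 10.95 in resting Gli2R Tg replicate 1 and 11.93 in its replicate 3, against 5.84 to 8.19 in the other resting arrays. Their fall with stimulation, called in 11 of 13 genes other than Cpb1 in Gli2R Tg, 5 of 13 in Gli2A Tg and 1 of 13 in WT cells, went with the number of high resting arrays, 2, 1 and 0 of 3.

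Probe sets without a gene symbol numbered 9160. With stimulation 2121 passed in WT, 2219 in Gli2A Tg and 2217 in Gli2R Tg cells, and between resting Gli2A Tg and WT cells 16 passed.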
